A study of Mus musculus with 9 samples.

How the data were processed

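RNA was measured in 9 primary pancreatic tumors of the KPC mouse line, 4 labelled Scrib WT (genotype written as KPF/+C) and 5 labelled Scrib null (KPF/+CSF/F). Per the labels' protocols the tumors were frozen, RNA was extracted from whole tissue with a column kit and mRNA libraries were made with an Illumina kit; the labels name polyA RNA as the molecule. Whether the kit kept strand is not given in the sources used here, so it is not known whether reads from overlapping genes on opposite strands were told apart.

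The deposited table held one column of estimated counts per tumor and one row per Ensembl gene. Per the submitters' processing notes the tools were Salmon 1.4.0 and DESeq 2, and the builds named were GRCm38 and mm10. The annotation release is not given in the sources used here. The deposited estimated counts were not normalized, were partly fractional, as a tool that shares reads among transcripts gives, and summed to a different total in each tumor. Genes with a near-identical copy depend on how those reads were shared. All 9 columns were used. The table had 54453 rows, none without a gene identifier, of which 54131 were given a symbol and coordinates from GENCODE M21 on GRCm38, and 23863 were at 0 in all tumors.

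Estimated counts were rounded to whole numbers, which moved no value by more than 0.5. Tumors were grouped by the genotype in the labels. Low genes were left out with edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 16169 genes. The main test was edgeR 4.0.16's quasi-likelihood test on TMM-normalised counts with no covariate, in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM was taken over the TMM-scaled library. Log2 CPM was computed with a prior count of 2.

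Gene lists, 49 in number, were written from textbook knowledge before the data were examined, and cover programmes linked to polarity, Hippo and ERK signalling, epithelial states, cell types that a whole tumor can hold and signs of RNA quality. The 46 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with a correlation estimated per list and with fry. Members were counted as changed when their p was under the threshold adjusted over the list alone, and over all genes tested. The level of a list in a tumor was the mean log2 CPM of its detected members, compared between groups with an exact two-sided permutation test over every split of the 9 tumors into 4 and 5, with Benjamini-Hochberg adjustment over lists. The smallest p this test can give is 0.00794.

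The genes named were fixed by a rule before the data were examined. Scrib came first. Next came the 10 higher and 10 lower genes with the smallest edgeR p among those whose groups did not overlap, with mean log2 CPM of at least 1 in a group and a symbol that was not a Gm number, a Rik clone, an identifier or a pseudogene copy. Up to 4 members with the smallest p came from each list described, and 16 further genes were set in advance whatever their p, of which 1 is not reported here. Rpl3-ps1 was named after its values were seen.

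Alternatives fixed before the data were examined were other normalizations, filters and thresholds, DESeq2 1.42.0, limma-voom with array weights, edgeR's robust fit, a test against a fold of 1.5, covariates for acinar, macrophage and T cell lists, sex, tumor identifier range and a surrogate variable (sva 3.50.0), and each tumor left out in turn. Alternatives chosen after seeing the data were leaving out both tumors that stood apart, leaving out genes within 10 Mb of Scrib, DESeq2 on the filtered genes and edgeR's likelihood ratio test. Transcripts of Rpl3 and Rpl3-ps1 were aligned with BLASTN.

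The tests were tested on simulated data for this comparison, with counts for 16169 genes drawn at the estimated dispersions and 200 genes changed. The edgeR test called 45% of genes changed 4-fold and 2% of those changed 2-fold, with 4 false calls among 51. DESeq2 called 81% and 20%, with 56 false calls among 157. With no gene changed, edgeR made 0 calls and DESeq2 made 25.

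Total estimated counts ranged from 10145830 to 27596832 per tumor. With a common biological coefficient of variation of 0.494, the spread between tumors rather than counting limited the precision of all but low genes. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 76.76 in every pair. Read-level checks, such as coverage of single Scrib exons, were not analysed here.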

Results

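Gene expression was measured by mRNA sequencing in 9 whole pancreatic tumors of the KPC mouse, a model of pancreatic ductal adenocarcinoma that arises in the pancreas of genetically engineered mice. The series compared 4 tumors labelled Scrib WT (tumors 2, 3, 6 and 9; genotype written as KPF/+C) with 5 labelled Scrib null (tumors 7, 14, 15, 18 and 23; KPF/+CSF/F). Scrib encodes a scaffold protein that sets apical-basal polarity in epithelia. The labels give each tumor an identifier of its own but do not say that each came from a separate mouse, so p-values measure the spread between these tumors. Estimated counts summed to 10145830, 13954780, 26502285 and 22241131 in the tumors labelled WT and to 20284114, 19281212, 27596832, 26061626 and 26349407 in those labelled null. In mega-counts (M) the means, 18.2 ± 7.49 M (SD, n = 4) and 23.9 ± 3.83 M (SD, n = 5), did not differ beyond the spread (exact two-sided permutation p = 0.222). In tumor WT 3 the 100 most abundant genes took 32.46% of counts, against 18.78% to 25.77% in the other tumors. Tumors null 7 and WT 3 lay at the ends of the first and second principal components, which held 29.6% and 26.4% of the variance. Xist and Y-linked transcripts marked tumors WT 3, null 7 and null 18 as male and the other 6 as female.

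Scrib mRNA was checked first because it bears on the labels. If F/F in the genotype marks a floxed allele, Scrib is deleted only in cells that expressed the Cre recombinase. Other cells of a whole tumor would still carry it, so the check is a weak one. The gene (chromosome 15, 76047158 to 76069784, GRCm38) had 70.5 ± 21.4 CPM (SD, n = 4) in the tumors labelled WT and 60.3 ± 24.6 CPM (SD, n = 5) in those labelled null, a difference smaller than the spread (exact two-sided permutation p = 0.524). In the edgeR quasi-likelihood fit its log2 fold change, null over WT, was -0.23 (SE 0.31, adjusted p = 0.712). The 95% confidence interval ran from 0.53-fold to 1.38-fold. Tumor null 7 held 102.2 CPM, more Scrib mRNA than any other tumor, and without it the log2 fold change was -0.48 (adjusted p = 0.377). The gene-level total does not show whether single exons were missing. Because Scrib mRNA did not set the groups apart, every direction given here is between tumors as labelled.

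**Figure D1:**
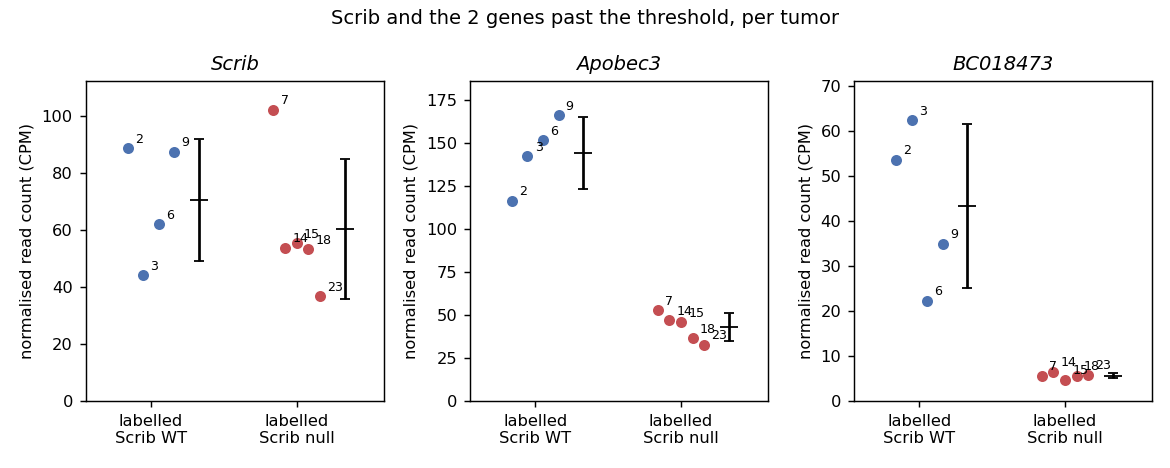
Normalised read count (CPM, vertical axis) of Scrib, Apobec3 and BC018473 in each tumor, by label; points are tumors with their numbers, and bars give the mean and SD. Scrib overlapped between the groups, with tumor null 7 highest at 102.2 CPM, while Apobec3 and BC018473 were lower in all 5 tumors labelled null than in all 4 labelled WT.

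Of 16169 genes tested, 2 fell in the tumors labelled Scrib null and 0 rose (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). BC018473 (chromosome 11, 116752167 to 116759373), annotated as an antisense RNA although no other annotated gene overlaps its span, fell by 2.92 on the log2 scale (SE 0.30, edgeR adjusted p = 0.0235), from 43.3 ± 18.1 to 5.73 ± 0.64 CPM (SD, n = 4 and 5). Apobec3 (chromosome 15, 79891659 to 79915906), a cytidine deaminase that restricts retroviruses, fell by 1.74 (SE 0.20, edgeR adjusted p = 0.0299), from 144 ± 20.8 to 43.0 ± 8.06 CPM. It lies 3.84 Mb from Scrib, and its end overlaps that of Cbx7 on the other strand, which had a log2 fold change of 0.23 (edgeR adjusted p = 0.793). At an unadjusted p under 0.05 edgeR listed 1236 genes as higher and 1623 as lower, and the groups did not overlap for 6.9% of genes. Chance gives 1.59% as a mean over all splits of the tumors. How widely single splits vary around that mean was not computed, so the gap was not tested. DESeq2 called 223 genes higher and 419 lower, and limma-voom called 1 and 5. Both edgeR calls were lost when any 1 tumor other than WT 6 was left out, and 1 remained without WT 6. They were also lost without both tumors WT 3 and null 7, with macrophage and T cell covariates and with the tumor identifier range as covariate, and 1 call was made with the sex or the acinar covariate. The log2 fold changes themselves changed little: that of gene BC018473 was -2.64 without both tumors, -3.00 (SE 0.45) with macrophage and T cell covariates and -2.96 (SE 0.33) with the identifier range, and that of gene Apobec3 was -1.80, -1.89 (SE 0.32) and -1.82 (SE 0.24). With each tumor left out they ran from -3.13 to -2.64 for gene BC018473 and from -1.83 to -1.67 for gene Apobec3.

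The 10 named genes with the smallest p among those higher in the tumors labelled null did not pass the adjusted threshold (edgeR adjusted p from 0.144 to 0.197). Rpia, an isomerase of the pentose phosphate pathway, had 34.3 ± 1.51 CPM in the WT and 74.9 ± 12.4 CPM in the null group. Mcm2, a subunit of the replicative helicase, had 66.7 ± 17.3 and 142 ± 18.9 CPM, and the ligand Wnt7a had 84.7 ± 13.3 and 183.9 ± 31.6 CPM. Log2 fold changes were 1.13 for the Polycomb gene Phc1, 0.83 for the ribosome biogenesis factor Bms1, 1.41 for the semaphorin receptor Plxna3, 0.99 for the kinesin light chain Klc3, 1.63 for Morc4, 1.45 for Tmem132a and 1.68 for Jrk, which lies 1.34 Mb from Scrib. Rpia, Wnt7a, Phc1, Mcm2 and Bms1 all lie on chromosome 6, whose genes as a whole had a median log2 difference of 0.039 relative to all genes (exact two-sided permutation p = 0.746). Among the genes lower in the null group, 8 more were named and did not pass (edgeR adjusted p from 0.144 to 0.169). The matrix-degrading protease gene Ctsk had 112.1 ± 64.8 CPM in the WT and 12.5 ± 6.69 CPM in the null group. The fatty acid carrier Fabp4 had 103.4 ± 72.3 and 16.3 ± 4.58 CPM, and the secreted ribonuclease Rnase4 had 171.6 ± 62.7 and 34.3 ± 14.1 CPM. Log2 fold changes were -2.62 for Serpina3g, -1.94 for the glucocorticoid-activating enzyme Hsd11b1, -3.51 for the chemokine scavenger Ackr4, -3.55 for Prap1 and -1.63 for the cyclophilin Ppic.

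Tight and adherens junction genes were higher as a list in the tumors labelled null (camera adjusted p = 0.00327; adjusted p = 0.579 with an estimated correlation). Their mean level was 6.52 ± 0.10 log2 CPM (SD, n = 4) in the WT group and 7.00 ± 0.10 (SD, n = 5) in the null group, with no overlap (exact two-sided permutation p = 0.00794, adjusted p = 0.183 over lists). Of 23 members 17 had a positive and 6 a negative fold change, and 0 changed adjusted over the list alone or over all genes in edgeR, with 7 at an unadjusted p under 0.05. Tjp1, a tight junction scaffold, had 110 ± 46.1 and 205.7 ± 52.3 CPM. Cingulin, Cgn, had 67.5 ± 17.6 and 103.4 ± 17.5 CPM, and plakoglobin, Jup, had 244.2 ± 125 and 442.9 ± 59.2 CPM. It was the 1 list that also passed fry (adjusted p = 0.0272), which asks whether the genes of a list move one way on balance. Cdh1, E-cadherin, had 723.5 ± 131 and 911.6 ± 218 CPM (edgeR adjusted p = 0.504). Without both tumors WT 3 and null 7 the list still differed by 0.48 (exact two-sided permutation p = 0.0286). The mean level of 13 non-epithelial lists was 3.6 to 4.02 log2 CPM in the tumors labelled WT and 1.71 to 3.71 in those labelled null (exact two-sided permutation p = 0.0397), so markers of other cells also differed between the groups. Null 7 and null 15, at the 2 ends of that null range, had junction levels of 6.92 and 7.04. Tumor WT 6, with a non-epithelial level of 3.6, had a junction level of 6.61.

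Polarity genes and the components of the Hippo pathway, a kinase cascade that restrains the coactivators YAP and TAZ, were also higher as lists (camera adjusted p = 0.0224 and 0.00327; both adjusted p = 0.699 with an estimated correlation), in tumors whose mean non-epithelial level was lower (exact two-sided permutation p = 0.0397). The polarity list did not pass without null 18 (adjusted p = 0.0502). In the polarity list 16 of 21 members had a positive fold change, and in the Hippo list 17 of 19. No member of either list passed edgeR adjusted over the list alone or over all genes, with 2 and 3 at an unadjusted p under 0.05. Pard3 had 52.7 ± 19.6 CPM in the WT and 102.5 ± 15.9 CPM in the null group. Partners and relatives of Scrib had log2 fold changes of 0.50 for Llgl1, 0.60 for Llgl2, 0.46 for Dlg1 and 0.80 for Dlg5. In the Hippo list the log2 fold changes were 1.12 for Amot, 0.91 for Wwc1, 0.72 for Taok1, 0.42 for Yap1 and 0.39 for Wwtr1, which encodes TAZ. YAP/TAZ target genes did not shift as a list, with 12 members above and 14 below 0 and a median log2 fold change of -0.03 (camera adjusted p = 0.811, with the opposite sign). Ccn1 and Ccn2, the targets most often measured, had log2 fold changes of -0.19 and -0.80, while Ankrd1 and Myof had 1.69 and 1.005 (edgeR adjusted p from 0.243 to 0.758). The sign of Ccn1 turned without tumor WT 2, and those of both Ccn genes turned with macrophage and T cell covariates. Ccn2 had 1337 CPM in tumor WT 2 against 411 to 650 CPM in the other tumors labelled WT.

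ERK output genes, transcribed or held in check downstream of the kinase ERK, were higher as a list (camera adjusted p = 0.000831; adjusted p = 0.699 with an estimated correlation), beside levels lower in all 13 non-epithelial lists (median difference -0.99). Of 16 members 3 rose adjusted over the list alone and 0 over all genes, where 6 had an unadjusted edgeR p under 0.05. These were the phosphatase Dusp4, from 59.5 ± 16.03 to 141.8 ± 39.0 CPM, the ephrin receptor Epha4, from 13.2 ± 6.82 to 46.2 ± 24.7 CPM, and the AP-1 subunit Fosl1, from 15.9 ± 4.04 to 34.9 ± 13.9 CPM. The list level was 5.92 ± 0.40 and 6.58 ± 0.23 log2 CPM (exact two-sided permutation p = 0.0238, adjusted p = 0.266 over lists). Trp53, which encodes a tumor suppressor, had 33.2 ± 27.8 and 18.1 ± 4.27 CPM (edgeR adjusted p = 0.320), with 74.5 CPM in WT 2, and its log2 fold change of -0.87 was -0.10 without that tumor. Proliferation genes were higher as a list (camera adjusted p = 0.00769; adjusted p = 0.699 with an estimated correlation), with 20 of 25 members above 0, and did not pass without null 14 (0.107) or WT 2 (0.0803). Of them 2 rose adjusted over the list alone and 0 over all genes, both subunits of the replicative helicase. Mcm6 went from 91.4 ± 18.5 to 173.6 ± 27.8 CPM, beside Mcm2. Mki67 had 72.6 ± 34.9 and 110.3 ± 59.5 CPM (edgeR adjusted p = 0.441).

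Genes of the classical subtype, a gastrointestinal-like state of pancreatic cancer cells, were lower as a list (camera adjusted p = 0.0015; adjusted p = 0.699 with an estimated correlation), with 21 of 22 members below 0. Of these 2 fell adjusted over the list alone and 0 over all genes. The lectin gene Lgals4 went from 1449 ± 1277 to 164.4 ± 95.2 CPM and Anxa10 from 367 ± 398.6 to 26.8 ± 19.2 CPM, and for Anxa10 the SD in the WT group was as large as the mean. Tff3, a secreted trefoil peptide, had 6.94 ± 4.89 and 1.42 ± 1.03 CPM. The list level, 5.97 ± 0.62 and 4.71 ± 1.05 log2 CPM, had an exact two-sided permutation p of 0.0635. It was 3.02 in tumor null 7 against 4.46 to 5.71 in the other tumors labelled null, and without null 7 the difference was -0.83 in place of -1.25. Levels of the hepatocyte and intestinal lists differed in the same direction, by -1.12 and -1.11 (exact two-sided permutation p = 0.0794 and 0.111), as did the mean non-epithelial level given above. Neither the basal-like and squamous list (camera adjusted p = 0.811) nor the ductal list (0.834) shifted, and Krt19 had a log2 fold change of -0.22 whose sign turned without tumor WT 3. The list of EMT and mesenchymal genes did not pass (camera adjusted p = 0.0541), but passed as lower with the strict filter (0.0281), on ranks (0.037) and without WT 3 (0.00122), WT 6 (0.0376), null 14 (0.0396), null 18 (0.0136), null 23 (0.0305) or both WT 3 and null 7 (0.00698). Vim had a log2 fold change of -1.08 (edgeR adjusted p = 0.293), with 1577 CPM in WT 2 against 283 to 848 CPM in the other tumors labelled WT.

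**Figure D2:**
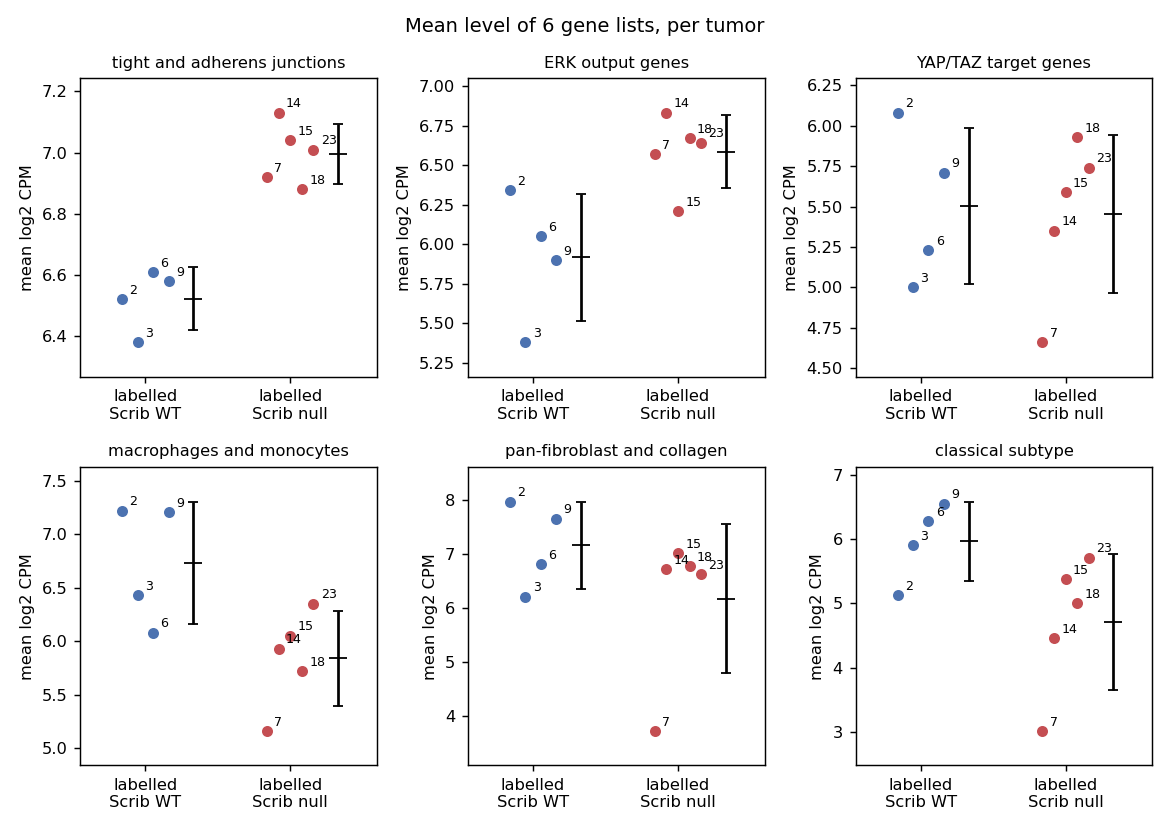
Mean log2 CPM (vertical axis) of 6 gene lists in each tumor, by label; points are tumors with their numbers, and bars give the mean and SD. Junction genes, at 6.52 ± 0.10 and 7.00 ± 0.10, did not overlap between the groups, and tumor null 7 held the lowest fibroblast level, 3.73.

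Markers of macrophages and monocytes were lower as a list in the tumors labelled null (camera adjusted p = 9.92e-06; adjusted p = 0.699 with an estimated correlation), with 20 of 20 members below 0. Of these 8 fell adjusted over the list alone and 0 over all genes, with 14 at an unadjusted edgeR p under 0.05. The Fc receptor Fcgr1 went from 21.9 ± 5.85 to 11.6 ± 1.97 CPM, the mannose receptor Mrc1 from 108.4 ± 64.4 to 36.1 ± 12.7 CPM, the chemokine receptor Ccr2 from 41.0 ± 15.0 to 16.2 ± 5.98 CPM and Trem2 from 38.0 ± 9.73 to 16.9 ± 7.56 CPM. The list level was 6.73 ± 0.57 and 5.84 ± 0.45 log2 CPM (exact two-sided permutation p = 0.0317, adjusted p = 0.266 over lists). Neutrophil markers were lower too (camera adjusted p = 0.00327; adjusted p = 0.699 with an estimated correlation), and of 14 members 2, the protease Mmp9 and the decoy receptor Il1r2, fell adjusted over the list alone and 0 over all genes. The neutrophil list did not pass without WT 3 (0.0578), whose level was 6.57 log2 CPM against 3.91 to 5.05 in the other tumors labelled WT, or without both WT 3 and null 7 (0.283), and the log2 fold change of gene Il1r2 was -1.49, or -0.64 without WT 3. Of the lymphoid lists, B and plasma cell markers passed camera (adjusted p = 0.00769) and so did T cell markers (0.0234), again with adjusted p = 0.699 for both with an estimated correlation. Mzb1, Cd79b and Jchain fell adjusted over the list alone, from 1.52 ± 0.77, 4.09 ± 2.49 and 14.7 ± 15.9 CPM to 0.17 ± 0.19, 1.03 ± 0.75 and 1.28 ± 1.28 CPM. No T cell marker did, the T cell list did not pass without WT 9 (0.105) or null 15 (0.0782), and Lck had 3.24 ± 1.04 and 1.77 ± 0.88 CPM. Among mast cell markers (camera adjusted p = 0.048; adjusted p = 0.699 with an estimated correlation) the protease genes Mcpt1 and Mcpt2 fell adjusted over the list alone. That list did not pass without WT 2 (0.109), WT 3 (0.0952), WT 6 (0.052), WT 9 (0.0622), null 7 (0.132), null 14 (0.0592) or both WT 3 and null 7 (0.19), nor in all 9 tumors with RLE scaling (0.0513) or on ranks (0.0793). The log2 fold change of gene Mcpt2 was -5.66, or -3 without WT 3. Ptprc, the pan-leukocyte marker CD45, had 41.7 ± 11.8 and 23.5 ± 8.64 CPM (edgeR adjusted p = 0.248).

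Lists of fibroblasts and vessels were lower as well. Camera gave adjusted p = 0.0053 for the pan-fibroblast, 0.00769 for the myofibroblastic and 0.0457 for the inflammatory fibroblast list. It gave 0.0216 for the list of antigen-presenting fibroblasts and mesothelium, 0.000831 for endothelium and 0.00769 for pericytes. Each had adjusted p = 0.699 with an estimated correlation. The antigen-presenting list also holds mesothelial genes such as Msln and shares Krt19 with the ductal list, so it is not a measure of fibroblasts alone. Without null 7 the pan-fibroblast (0.0655), inflammatory (0.212) and antigen-presenting (0.132) lists did not pass, and without WT 2 neither these (0.09, 0.18 and 0.127) nor the myofibroblastic list (0.0838) did. The inflammatory list also did not pass without null 18 (0.0868), null 23 (0.159), WT 9 (0.0589) or both WT 3 and null 7 (0.16), nor with the strict filter (0.0722). Of the pan-fibroblast members 18 of 19 were below 0, and the protease gene Fap had 15.3 ± 5.80 and 5.16 ± 2.61 CPM. Col1a1 had 1705 ± 1500 and 1063 ± 527.4 CPM, and its level in tumor null 7 was 141 CPM. Further log2 fold changes were -1.72 for Lum, -1.24 for Postn, -1.69 for Hopx, -0.97 for Msln, -1.33 for Egfl7, -1.59 for Cldn5, -1.11 for Rgs5 and -1.22 for Kcnj8. Of these 6 lists only the inflammatory one had members that fell adjusted over the list alone, namely Cfd, Ccl7 and Lpl. Fabp4 and Cfd, both abundant in fat, fell adjusted over the adipocyte list alone. Cfd went from 17.4 ± 19.6 to 0.15 ± 0.23 CPM. Tumor null 7 stood below the other tumors in fibroblast level, at 3.73 log2 CPM against 6.63 in the next lowest tumor of its group. Without it the pan-fibroblast difference was -0.38 in place of -0.99, that of endothelium -0.48 in place of -0.90 and that of pericytes -0.55 in place of -1.01, while the last 2 lists still passed camera (0.0088 and 0.023).

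Acinar markers did not shift (camera adjusted p = 0.874; median log2 fold change -1.06, level difference 0.18), but passed as higher without WT 6 (0.0227), whose level was 3.55 log2 CPM against -0.87 or less in the other tumors labelled WT, and Cela1 had 34.3 ± 25.2 and 10.3 ± 8.78 CPM (edgeR adjusted p = 0.254). Markers of red blood cells (camera adjusted p = 0.0165) and mitochondrial mRNAs (0.0234) were lower as lists, both with adjusted p = 0.699 with an estimated correlation. The red blood cell list did not pass without WT 2 (0.0885), WT 3 (0.056), null 7 (0.0545), null 14 (0.0592) or both WT 3 and null 7 (0.16), nor the mitochondrial list without WT 2 (0.0957), WT 6 (0.119), null 15 (0.144) or null 23 (0.172). Hba-a1 had 348.3 ± 182.9 and 178.8 ± 202.3 CPM, and mt-Nd4 had a log2 fold change of -0.57. Immediate early genes, a sign of handling, did not shift (camera adjusted p = 0.244). Of 46 lists tested 20 passed camera, 5 higher and 15 lower, 0 passed with an estimated correlation, and 0 levels passed the exact test after adjustment, where 6 had an unadjusted p under 0.05; a single level at the smallest possible p could not pass. In the lists that passed, the estimated correlation was 0.016 for junction genes, 0.101 for polarity genes and higher in the rest. It was 0.52 for macrophages, 0.822 for the pan-fibroblast list and 0.909 for ribosomal protein genes. All lay above the preset 0.01, so the preset p-values are too small where these correlations hold. Without tumor WT 2, 13 lists passed. Other lists that passed only in some alternatives were the hepatocyte list (camera adjusted p = 0.0541), lower with the strict filter (0.0138) and without WT 3 (0.0143), WT 6 (0.0193), WT 9 (0.019), null 23 (0.0305) or both WT 3 and null 7 (0.027), and glycolysis, higher without WT 3 (0.00281) or both (0.000595). Lymphatic endothelium was lower without WT 3 (0.0206) or both (0.0359), skeletal muscle without WT 6 (0.046), WT 9 (0.0378) or null 23 (0.0429), and cholesterol synthesis without null 14 (0.0137), while islet genes were higher without WT 2 (0.0383) and the unfolded protein response without both (0.0359).

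Ribosomal protein genes were lower as a list (camera adjusted p = 0.00769; adjusted p = 0.713 with an estimated correlation), and Rpl3 alone fell adjusted over the list alone. The list did not pass without WT 3 (0.515), whose level was 11.29 log2 CPM against 9.2 to 10.54 in the other 8 tumors, WT 6 (0.052) or null 23 (0.076). Rpl3 (chromosome 15, 80077791 to 80091868) had 1804.9 ± 846.2 CPM in the WT group and 435.2 ± 157.5 CPM in the null group, while its processed copy Rpl3-ps1 (chromosome X, 13202571 to 13203780), chosen after its values were seen, had 5.96 ± 8.09 and 885.2 ± 316.4 CPM. The copy's annotated transcript matches that of Rpl3 at 99.835% of 1210 bases, so the 2 values depend on how shared reads were assigned. In each of the 5 tumors labelled null the copy was given 1.975 to 2.132 times the count of Rpl3, and in each of the 4 labelled WT 0.019 times or less. Their summed CPM, 1810.9 ± 841.2 and 1320.4 ± 473.6, did not differ beyond the spread (exact two-sided permutation p = 0.317).

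**Figure D3:**
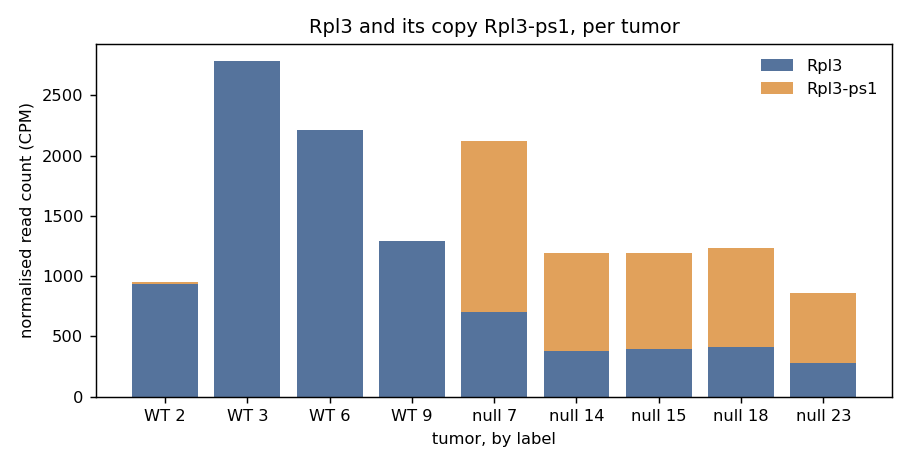
Normalised read count (CPM, vertical axis, from 0) assigned to Rpl3 and, stacked on it, to Rpl3-ps1 in each tumor. Every tumor labelled null had about 2 counts of the copy per count of Rpl3 (1.975 to 2.132), and the tumors labelled WT had 0.019 or less.

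**Figure D4:**
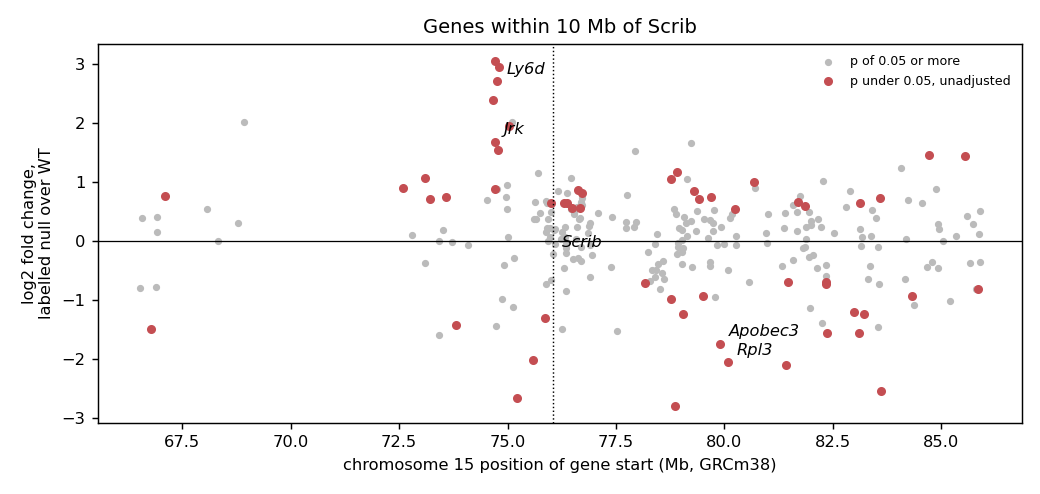
Log2 fold change, labelled null over labelled WT (vertical axis), of each tested gene within 10 Mb of Scrib, by gene start on chromosome 15 (GRCm38); red points had an unadjusted edgeR p under 0.05 and the dotted line marks Scrib. Of 264 genes in the window 56 were below that p, 33 higher and 23 lower, which is 21.2% against 17.7% of all genes tested.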

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

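The tests of copy number in both windows, of the summed Rpl3 counts, of the stromal lists without tumor null 7, of all stromal lists at once, of chromosome 6 against its leading genes and of the chromosomes of the leading genes were chosen after the result was seen.

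Within 10 Mb of Scrib only Apobec3 passed edgeR's adjusted threshold (Rpl3 adjusted p = 0.172), and 21.2% of genes had an unadjusted p under 0.05 against 17.7% of all genes tested, while each tumor fell on the side of its label in Apobec3 and in the share of Rpl3 counts given to Rpl3-ps1. A copy-number change of the whole 10 Mb window as the sole source of its 56 genes at an unadjusted p under 0.05 is argued against. Of these 58.9% shared a sign (exact 95% interval 45% to 71.9%). A smaller change of the window stays open, since 17.7% of all genes reached that p and many of the 56 need not come from it. One within 5 Mb also stays open, with 26 of 37 such genes higher (70.3%, 53% to 84.1%). The median over its 175 genes was 0.192 relative to all genes, which other splits exceeded (exact two-sided permutation p = 0.302, up to 0.343 in size in other splits, 0.067 to 0.287 with each tumor left out). Reads of Rpl3 given to its copy may account for both Rpl3 values, since the sum differed by -0.39 on the log2 scale (SE 0.41) where Rpl3 alone differed by -1.99. A segment of other strain origin carried with the targeted allele remains a candidate explanation: without Apobec3, Rpl3 and Jrk, 21.8% of genes within 10 Mb of Scrib had a limma p under 0.05 against 17.5% elsewhere, an excess of 4.3 points (one-sided exact permutation p = 0.0556). For Rpl3, the copy held 1.975 to 2.132 times its count in each tumor labelled null, while their sum there ran from 858 to 2122.7 CPM. A change in the expression of Rpl3 alone would not give such a steady ratio, so these values argue against it for this pair. The read sequences were not examined. No segment was genotyped and Scrib mRNA did not separate the groups. For the other genes linkage and an effect of the labelled genotype both stay open, as either would follow the labels.

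Of the 10 leading higher genes 5 lie on chromosome 6, which holds 5.1% of the genes tested. Their log2 fold changes ran from 0.83 to 1.13, farther than chromosome 6 moved as a whole. The median over its 823 genes was 0.039 relative to all genes, and 0.13 at most with a tumor left out. It was 0.101 at most in a 30 Mb stretch and 0.207 at most in size in any other split. This comparison cannot decide on a gain, since the leading genes were picked for small p and so have large changes. A gain of the chromosome therefore stays open. By the rule set in advance, a gain was argued against only if the median did not lie above that of all genes, which was not the case. With fibroblast and macrophage levels as covariates the median was -0.019, and after a fit on GC content and transcript length it was 0.085. Neither correction could decide, as the chromosome showed no shift to correct (exact two-sided permutation p = 0.746, and -0.023 without WT 2), so cell shares, GC content and length stay open. Ranked by limma, 4 of the 10 leading genes lay on chromosome 6, and 16 splits of the tumors, the real one included, had as many on a single chromosome.

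Markers of 13 non-epithelial cell types were lower in level in all 13 lists, by a median of -0.99. Tumor null 7 may contribute, since without it the median was -0.67 with 12 lists lower, but its removal did not end the difference, and too few tumors remain to tell. A smaller share of all non-epithelial cells in the tissue taken would lower all lists alike; dendritic cells stood 0.82 above the mean of the other lists (exact permutation p = 0.00794) and Schwann cells 1 above (0.0397), but a single list at the smallest possible p could not pass after adjustment (0.103), and all lists tested at once gave p = 0.468, which leaves that explanation open. The mean over the lists had an exact two-sided permutation p of 0.0397, and 0.0571 without null 7. A biological effect of the labelled genotype on the stroma stays open and untested, and how the tissue was sampled is not given in the labels.

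Taken alone, the count of edgeR calls passed the 0.05 level against other splits of the tumors. The real value was 2 and the highest other 3, and 3 of 100 splits drawn, the real one included, gave as many. For genes at an unadjusted p under 0.05 the real value was 2859 and the highest other 2872, with 2 of 100 splits as large. That other split set WT 3, WT 6, WT 9 and null 15 apart and so differs from the labels by 1 exchange of tumors. Even taken alone, DESeq2 on the filtered genes did not pass the 0.05 level, with 633 calls against a highest other of 803 and 3 of 24 splits as large. Neither did the 20 gene lists, with a highest other of 24 and 8 of 100 splits as large. These shares were not adjusted for the number of counts tested, so chance is not excluded for any of them. With no gene changed in simulated counts DESeq2 made 25 calls.

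Single tumors far from the rest of their group were found by Dixon's Q test in 25 of 264 groups of values. Chance gives about 1 in 20 only for independent, normally distributed values. CPM values are skewed and the lists share genes, so the 25 cannot be set against that share. Tumor null 7 accounted for 12 of the 25. It was high for Scrib (102 CPM), Plxna3 (50.7 CPM) and Rpl3-ps1 (1421 CPM). It was low for Col1a1 (141 CPM), Fap (0.656 CPM) and the levels, in log2 CPM, of TGF-beta targets (5.95), EMT genes (3.52), pan-fibroblast genes (3.73), myofibroblastic genes (3.64), endothelium (2.38), pericytes (1.2) and lymphatic endothelium (-0.33). Tumor null 15 was high for Rnase4 (58.5 CPM), Ackr4 (0.582 CPM) and Hba-a1 (528 CPM). Tumor null 14 was high for Mki67 (214 CPM) and the unfolded protein response (7.1 log2 CPM), and null 18 was high for Myof (887 CPM) and low for histone mRNAs without a polyA tail (2.03 log2 CPM). Among the tumors labelled WT, WT 9 was high for Llgl2 (107 CPM), WT 2 for Trp53 (74.5 CPM) and p53 targets (5.67 log2 CPM), WT 3 for Mcpt2 (2515 CPM) and Il1r2 (104 CPM), and WT 6 for acinar markers (3.55 log2 CPM).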

How the results depend on the processing

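Leaving out both tumors that stood apart, leaving out genes near Scrib, DESeq2 on the filtered genes and edgeR's likelihood ratio test were chosen after seeing the data. No paired analysis was possible because the groups share no replicate number. The count of 2 changed genes stayed at 2 with RLE, upper-quartile or library-size scaling, the strict filter, the robust fit, the abundant specialised genes left out and an adjusted p under 0.1. It was 7 with no filter, 6 with limma-voom, 3 with a surrogate variable, 642 with DESeq2 and 633 with DESeq2 on filtered genes, and 312 with the likelihood ratio test. It was 1 for a fold above 1.5, with the acinar covariate, with the sex covariate and with genes near Scrib left out, which removes Apobec3. It was 0 with macrophage and T cell covariates, with the tumor identifier range as covariate and without both tumors that stood apart, and 0 to 1 with each tumor left out. The cause of these differences was not tested, except that fewer tumors or added covariates leave fewer degrees of freedom. Scrib kept a negative log2 fold change and did not pass the threshold in any alternative, from -0.63 without both tumors that stood apart to -0.10. Gene lists past the threshold numbered 0 with an estimated correlation and 1 with fry, 13 to 22 with each tumor left out, and 19 to 21 otherwise. List levels passed under no alternative, but a single level at the smallest possible p could not pass after adjustment over 46 lists, so this says nothing about stability. Library size differed by 3.02 to 8.47 M counts with each tumor left out, never past the threshold.

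With macrophage and T cell covariates the sign turned for Ccn1 (0.23), Ccn2 (0.24), Vim (0.11), Krt19 (0.11), Ptprc (0.10), Col1a1 (1.56), Foxf2 (0.063), Fbln1 (0.16), Myl9 (0.13), Slpi (0.087), Cd74 (0.21), Hdc (0.074) and Cidec (0.15). Without WT 2 it turned for Ccn1 (0.011), and without WT 3 for Krt19 (0.072), S100a9 (0.20) and Hdc (0.54). With other single tumors left out the lowest value was -0.472 for gene Ccn1, -0.416 for gene Krt19, -3.202 for gene S100a9 and -1.185 for gene Hdc. Without both tumors that stood apart it turned for Krt19 (0.20), S100a9 (0.44) and Hdc (0.74), and with limma-voom for Hdc (0.019). None of these genes passed the test either way, and the cause was not tested. With 10145830 counts in the shallowest tumor, depth limits only low genes such as Mzb1.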

Other observations

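Tuft cell and metaplasia genes did not pass as a list (camera adjusted p = 0.129, and 0.013 and lower without WT 6), yet 3 of 12 tested members fell adjusted over the list alone and 0 over all genes in the tumors labelled null, with 7 at an unadjusted edgeR p under 0.05. They were the tuft cell adaptor Sh2d6, from 3.93 ± 4.13 to 0.41 ± 0.26 CPM (SD, n = 4 and 5), and 2 genes of leukotriene synthesis that tuft and immune cells share, Alox5ap, from 58.1 ± 28.9 to 21.1 ± 9.57 CPM, and Ltc4s, from 17.9 ± 11.5 to 6.25 ± 2.45 CPM. The log2 fold change of gene Ltc4s was -0.96 without WT 2. The adipocyte list level was 3.72 ± 0.52 and 2.49 ± 0.41 log2 CPM, with an exact two-sided permutation p of 0.00794 and an adjusted p of 0.183 over lists; by camera the list passed only without WT 9 (0.0238) among the alternatives run.

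By chromosome, genes on chromosome 16 had a median log2 difference of -0.187 relative to all genes (exact two-sided permutation p = 0.00794, adjusted p = 0.159 over 20 chromosomes) and those on chromosome 19 one of 0.204 (0.0476, adjusted 0.476). With 20 chromosomes no single one could pass, because the smallest possible p adjusts to 0.159.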
